A study of Mus musculus with 2 samples.

How the data were processed

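RNA came from splenic B cells of C57BL/6 mice that had been purified by depletion of CD43-positive cells, per the labels. The cells were cultured in lipopolysaccharide (25 µg/ml) and interleukin-4 (10 ng/ml), exposed to retroviral supernatant for 20 h with the cationic polymer polybrene (8 µg/ml), and sorted for green fluorescence on day 2. RNA integrity numbers were 9.7 to 9.8, and 2 µg of RNA was labelled with Cy3 or Cy5 per the labels. The labels state 1 biological replicate per vector and 2 hybridisations with exchanged dyes. Both arrays therefore count as 1 replicate. They shared a slide, so no batch separates them.

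Per the file headers, Agilent Feature Extraction 9.1.3.1 made the deposited scanner files. They hold the mean intensity of each spot and the median intensity of its local background in Cy3 and Cy5, on a linear scale with no correction. They also hold the processed intensity of each channel, from which the software had subtracted background and removed a dye trend by lowess, per the file headers. The deposited log10 ratio is Cy5 over Cy3 of those processed signals, not turned for the dye exchange. A p-value of each log10 ratio comes from the software's error model within an array, per the file headers, and says nothing of variation between cultures. The authors also deposited a table of log2 ratios for both arrays. Its row identifiers matched no probe column and its rows were not named through them. For all 40929 probes with 1 spot, the pair of values matched the log2 ratio of processed signals within 0.0001, after the sign of array 2 was turned and constants of 0.0011 and 0.0327 were added. This comparison settled scale, direction and centring. Probes with several spots were not matched. Where the deposited table is used below, its values are these log2 ratios of processed signals with the constants added. They are therefore not independent of the scanner's log ratio. The column medians were -0.0626 and -0.0704.

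Each array had 45018 spots, of which 43379 were not controls, for 41174 probes. Ratios were computed in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with an offset of 50 on the mean signal and local median background, and each array was normalised by loess with control spots at weight 0. Spots marked as outliers were left out (7 on array 1 and 21 on array 2). Saturated spots were kept. Spots of a probe were averaged, and of several probes of a gene the brightest was used. Of 5752 genes with more than 1 measured probe, 2397 had probes whose mean ratios differed in sign. Probes were named through a RefSeq gene table (GRCm38.p6), by accession for 22951 probes, by symbol for 6659 and by synonym for 3109. The remaining 8455 kept the file's name. No coordinates are given, since no build is named for the array.

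Between 64.7% and 67.7% of spots were well above background in a channel. On array 1, 163 spots were saturated in Cy3 and 538 in Cy5, and on array 2 the numbers were 71 and 562. A gene was measured when well above background in both RNAs on both arrays, which left 10091 gene names out. For a gene well above background in 1 RNA, the ratio is a bound, computed after loess and Aquantile from the bright RNA's mean and the higher of the dim signal and the lowest signal among probes well above background. The number of arrays limits the precision.

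The lists, the rules and the main settings were fixed before the data were examined. A gene counted as higher or lower when its mean log2 ratio was at least 1 (2-fold) and each array alone reached 1.5-fold. For counts at 1.5-fold, the mean had to reach 1.5-fold with the same sign on both arrays. No minimum was then set for either array alone. Named genes were all measured literature targets of miR-181, the 12 highest and 12 lowest genes by the smaller of the arrays' absolute ratios, and up to 4 members per list with the largest mean ratio of the same sign on both arrays. Names that are clones or predicted genes were skipped (28 among the higher genes, 0 among the lower). Where fewer than 12 genes passed 2-fold, the ranking went on below it. Results for some genes that these rules name are not reported here. Each of 29 lists was described by the median ratio of its measured members and its percentile among 10000 random lists of the same size, matched on intensity in 10 bins, with seed 11. A list stood apart below percentile 2.5 or above 97.5. The dye contrast was counted by the same rule.

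The steps were tested on simulated arrays with 25812 probes of miR-181b over control, of which 200 were changed. Of 50 probes simulated at -2.5, 100% were found, and of those at 2.5 also 100%. At -1.5 the share was 78% and at 1.5 it was 76%. Of 25612 unchanged probes, 0 were called. Their simulated noise had an SD of 0.15 per spot, and a dye effect with an SD of 0.3 per probe cancelled between the arrays. Such noise could hardly reach 2-fold, so this result says little about false calls on the real arrays. Of 50 lists shifted by 0.3, 50 stood apart, and of 50 unshifted lists, 1 did. Shifts smaller than 0.3 were not simulated, although most lists below had smaller medians.

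Alternatives were no background subtraction, a normexp offset of 16, the scanner's log ratio, the deposited log2 table, median centring without loess, Aquantile, no filter on dim probes, only genes above the median intensity, the mean of all probes of a gene, each array alone, a 1.5-fold threshold and a scanner p-value under 0.01 on both arrays. Scaling between the arrays and leaving saturated genes out were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the lists and matplotlib 3.10.9 for the plots. A planned comparison of genes with and without a miR-181 site in their annotated 3' untranslated region was not analysed here, as no genome with untranslated regions was used.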

Results

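Messenger RNA levels were compared between activated mouse B cells that carried a retroviral vector for the microRNA miR-181b and B cells that carried a control vector. The cells were primary splenic B lymphocytes of C57BL/6 mice, stimulated with lipopolysaccharide and interleukin-4, a combination that drives proliferation, antibody class switching and antibody secretion. Both vectors also encoded green fluorescent protein, and fluorescent cells were sorted on day 2. The series holds 1 RNA sample per vector. Both RNAs were hybridised together on 2 whole mouse genome arrays with the dyes exchanged, so that array 1 carried the miR-181b RNA in Cy5 and array 2 carried it in Cy3. The arrays are technical repeats of 1 pair of RNAs. No test between conditions was possible, no p-value is given, and differences below describe these RNA samples. Each log2 ratio is miR-181b over control, given as the mean of both arrays with the distance of either array from that mean as technical spread (±). Between 64.7% and 67.7% of spots were well above background in each channel, and 17579 genes were measured in both RNAs on both arrays.

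Of 21 literature targets of miR-181, 16 were measured, and their median was -0.04 (0.01 on array 1 and -0.16 on array 2). That median lay at percentile 17.3 of random lists of the same intensity, although on array 2 alone it lay at percentile 2.31. Among them, the kinase gene Nlk was at -0.31 ± 0.14, with another probe at -0.10, and the activation marker gene Cd69 at -0.10 ± 0.04. The anti-apoptotic Bcl2 was at 0.05 ± 0.03. Of these 16 genes, 4 were lower and 1 was higher on both arrays, and 11 had opposite signs. The probes of Bcl2, Cyld, Xiap and Atm differed in sign, and Mcl1 was saturated in Cy5 on both arrays. In the list of class switching and hypermutation factors (30 measured), the median was 0.02 (0.05 on array 1 and -0.04 on array 2), at percentile 68.1, with the mismatch repair gene Msh6 at -0.38 ± 0.15 and the base excision repair gene Apex1 at 0.37 ± 0.21.

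In the miR-181b cells 17 genes were at least 2-fold lower and 1 was at least 2-fold higher. Of the 17 lower genes, 5 belonged to the list of glycolysis and hypoxia genes. Bnip3, a hypoxia-inducible mediator of mitophagy, was 5.46-fold lower (-2.45 ± 0.16). The lactate exporter Slc16a3 was 4.02-fold lower (-2.01 ± 0.11), and Mgarp, a mitochondrial protein gene, was 3.69-fold lower (-1.88 ± 0.15). Pdk1, which encodes a kinase that inhibits pyruvate dehydrogenase, was 2.80-fold lower (-1.48 ± 0.01). Ndrg1 and the collagen prolyl hydroxylase gene P4ha2 were each 2.59-fold lower. The same ranking held Smtnl2 (-1.53 ± 0.04), the lipoprotein receptor gene Vldlr (-1.36 ± 0.05), Prelid2 (-1.35 ± 0.06), the phosphoglucomutase gene Pgm1 (-1.34 ± 0.07), the adenylate kinase gene Ak4 (-1.21 ± 0.04) and the glycogen phosphorylase gene Pygl (-1.11 ± 0.02). The remaining genes past 2-fold were Slc2a1, Cox7a1, Egln3, Fam162a and Abhd18, of which the last 4 were named after their values were seen. Further probes gave smaller values for Vldlr (-0.50), Fam162a (-0.36, against -1.09) and Abhd18 (-0.66, against -1.04).

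**Figure D1:**
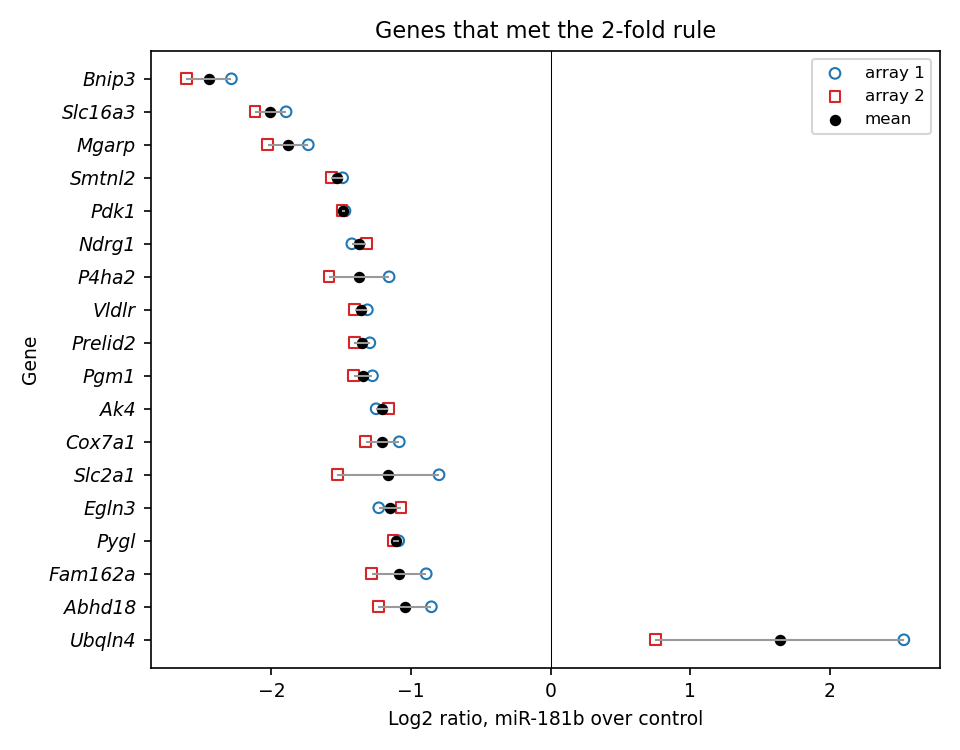
Log2 ratio (x axis, miR-181b over control) of each gene that met the 2-fold rule (y axis), with circles for array 1, squares for array 2, filled points for their mean and a line joining both arrays. The 17 lower genes lie between -2.45 and -1.04, while for Ubqln4 the arrays lie far apart.

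The only gene past 2-fold in the other direction was Ubqln4, which encodes a ubiquilin, at 1.64 ± 0.89. Its value was 2.53 on array 1 and 0.75 on array 2. Below 2-fold, the next higher genes with a gene symbol were mainly variable segments of the immunoglobulin kappa light chain. In this ranking 28 clone or predicted names were skipped. No heavy-chain V gene was among those named, although as a group their median was 0.66, against 0.69 for kappa V genes. Igkv3-12 was at 0.94 ± 0.23, Igkv4-63 at 0.88 ± 0.14 and Igkv4-72 at 0.85 ± 0.18, and a pair of segments of the Igkv1 group stood at 0.98 ± 0.32 and 0.90 ± 0.12. Igkv8-16, Igkv4-86 and Igkv6-14 were between 0.68 and 0.80. The same ranking named Atcay (0.73 ± 0.03), the eosinophil granule gene Prg2 (0.70 ± 0.02) and the apolipoprotein gene Apoe (0.64 ± 0.05). At 1.5-fold on the mean, with the same sign on both arrays but no minimum for either, 144 genes were higher and 90 lower. Without loess, each array being centred on its median, the 1.5-fold counts were 6 higher and 908 lower. The 2-fold counts were then 0 and 56, and they were 3 and 33 with the scanner's own log ratio.

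The contrast between dyes, counted by the same rule, gives the technical background. It held 69 genes past 2-fold, all of them brighter in Cy3 and all saturated in at least 1 channel. Without loess it held 0 such genes, and with the scanner's own log ratio it held 125, of which 10 were brighter in Cy5. None of the genes past 2-fold between the RNAs was saturated. Among the 17142 genes that were never saturated, the dye contrast held 0 genes past 2-fold and 43 past 1.5-fold, against 133 higher and 88 lower genes in the comparison of RNAs. Another 178 genes were well above background only in the miR-181b RNA and 11 only in the control RNA. Their bounds reached at most 1.21-fold and 1.26-fold, so no difference of 1.5-fold could be shown for them, and larger differences are not excluded.

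Of 29 gene lists, 5 had a median below and 6 had a median above the middle 95% of random lists matched on intensity. By chance 1.45 would be expected if the members of a list varied independently, which was not tested. In the dye contrast 8 lists stood apart, among them 4 of the 6 lists above (endoplasmic reticulum stress, plasma cell, B cell identity and immunoglobulin) and 0 of the 5 low lists. All 5 low lists were low on each array. The list of glycolysis and hypoxia genes (24 measured) had a median of -0.57, with -0.86 on array 1 and -0.44 on array 2, below every random list. In it 18 genes were lower and 0 were higher on both arrays, and 12 were at least 1.5-fold lower. Beside Bnip3, Pdk1 and Ndrg1, the glucose transporter gene Slc2a1 was at -1.16 ± 0.36. Without its 6 saturated members the median was -0.69. Cholesterol synthesis genes (20 measured) had a median of -0.34, and 15 were lower on both arrays. Examples are the sterol carrier gene Stard4 (-0.76 ± 0.27), Msmo1 (-0.67 ± 0.09), the synthase gene Hmgcs1 (-0.66 ± 0.09, with another probe at -0.19) and Hsd17b7 (-0.57 ± 0.03). Insig1 and Mvk, noted after their values were seen, had positive means of 0.19 and 0.21, and another probe of Mvk gave 0.04. Without loess the medians of the 5 low lists were between -0.98 and -0.40, or between -0.77 and -0.20 relative to the median of all genes (-0.20), and all 5 stayed below random lists.

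Mitotic genes (23 measured) had a median of -0.25, with -0.22 on array 1 and -0.26 on array 2, and 17 were lower and 0 higher on both arrays. The checkpoint kinase gene Bub1 was 1.60-fold lower (-0.68 on both arrays), the kinesin gene Cenpe was at -0.47 ± 0.19 (its other probes between -0.56 and -0.30) and Aurkb at -0.46 ± 0.12. Kif20a was at -0.42 ± 0.07. The direction of DNA replication genes (24 measured) was not settled, since their median was 0.15 on array 1, at percentile 99.97, and -0.04 on array 2, at percentile 32.6. On the mean it was 0.07, at percentile 93.0, with Fen1 at 0.45 ± 0.30 and Mcm2 at 0.32 ± 0.16. Histone genes (11 measured) had a median of -0.23, or -0.135 with the mean of all probes of a gene, and H3c1 was at -0.57 ± 0.18 and H1f5 at -0.48 ± 0.02. Of the list of MAP kinase feedback and immediate early genes (24 measured), 11 were lower and 3 higher on both arrays. Its median was -0.14, with -0.09 on array 1 and -0.16 on array 2, and -0.09 after scaling between the arrays, chosen after seeing the data. The lowest were Ier3 (-0.74 ± 0.06), Egr2 (-0.69 ± 0.10), Egr1 (-0.68 ± 0.13) and Nr4a1 (-0.63 ± 0.16).

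The list of endoplasmic reticulum stress genes (21 measured) was the only list above random lists on both arrays, with a median of 0.36 (0.27 on array 1 and 0.54 on array 2). In it 15 genes were higher and 1 lower on both arrays. Xbp1, a transcription factor of secretory cells, was 1.98-fold higher (0.99 ± 0.49), Sel1l was at 0.87 ± 0.50 with another probe at 0.37, Pdia4 at 0.73 ± 0.31 and Sdf2l1 at 0.67 ± 0.08. Without loess its median was -0.016, against -0.20 for all genes, and it still lay at percentile 100. Plasma cell genes (17 measured, 4 of them saturated) had a median of 0.19, with 0.10 on array 1 and 0.37 on array 2, and 11 were higher and 0 lower on both arrays, although the list was at percentile 97.3 on array 1 alone. Beside Xbp1, Edem2 was at 0.74 ± 0.57, Ell2 at 0.48 ± 0.08 and the transcription factor gene Irf4 at 0.36 ± 0.19. The p53 list (median 0.13, 16 measured) and the interferon list (median 0.13, 27 measured) were above random lists on the mean, with Cdkn1a at 0.28 ± 0.16 and Isg20 at 0.45 ± 0.12. On array 2 alone their percentiles were 91.3 and 96.8. Without loess the medians of the plasma cell, p53 and interferon lists were -0.19, -0.25 and -0.21, and the p53 list, at percentile 94.75, then lay inside the random range. The B cell identity list had a median of 0.15 on the mean but -0.13 on array 1 and 0.39 on array 2, so its direction was not settled. After scaling between the arrays it was at 0.04, inside the random range. The direction was not settled either for the list of immunoglobulin transcripts (5 measured), which holds constant-region, joining-chain and lambda variable transcripts (-0.41 on array 1 and 1.27 on array 2), 4 of which were saturated.

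**Figure D2:**
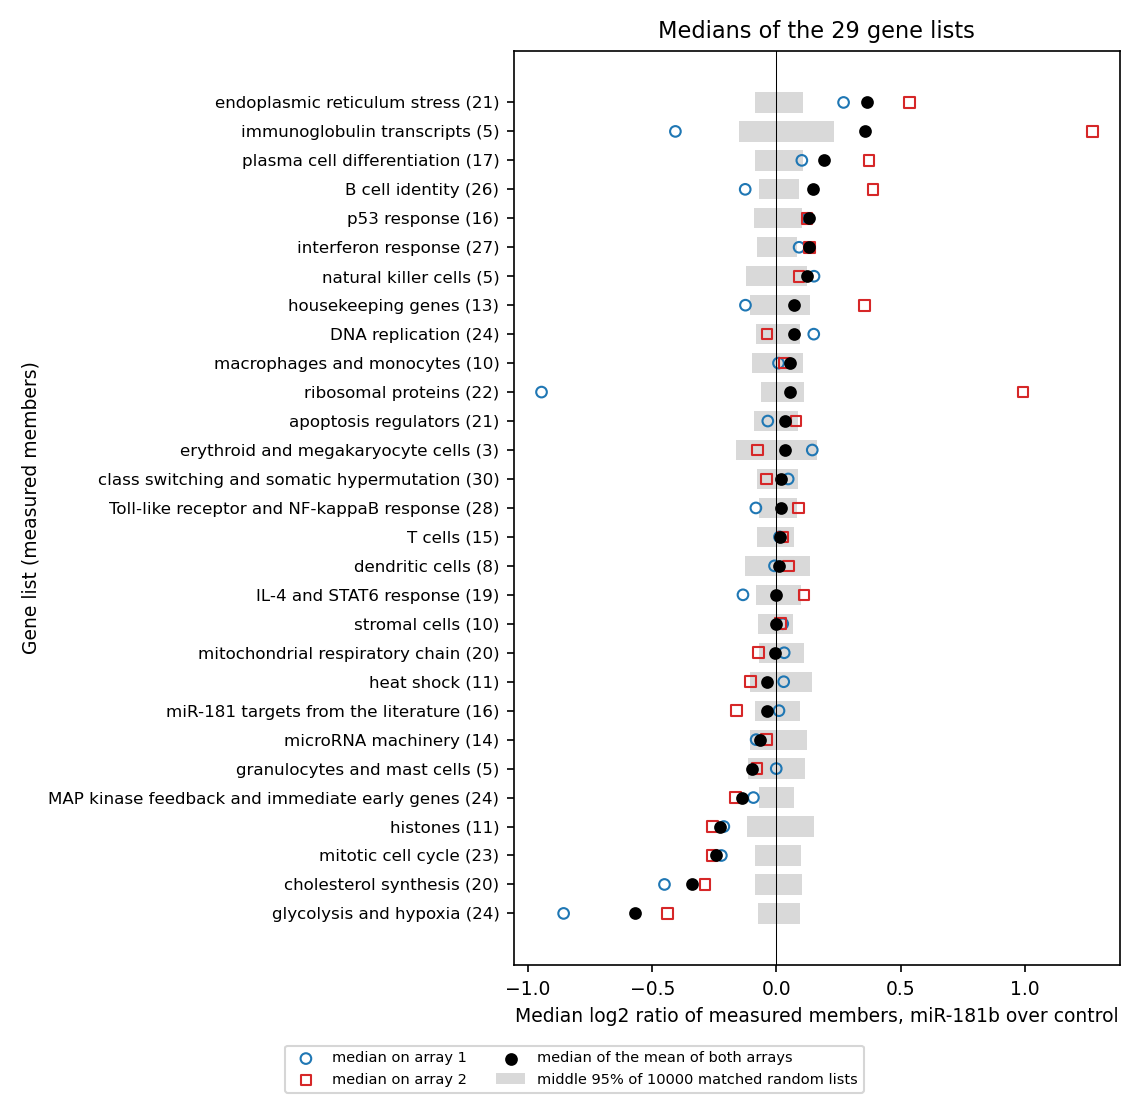
Median log2 ratio (x axis, miR-181b over control) of each of 29 gene lists (y axis, with the number of measured members), with circles for array 1, squares for array 2, filled points for the mean of both arrays and grey bars for the middle 95% of 10000 matched random lists. Glycolysis and hypoxia genes lie lowest at -0.57 and endoplasmic reticulum stress genes highest at 0.36, and the saturated ribosomal protein genes lie at -0.95 on array 1 and 0.99 on array 2.

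No list of markers of another cell type stood apart in the main setting. Median log2 ratios were 0.01 for T cells (15 measured), 0.06 for macrophages and monocytes (10), and 0.01 for dendritic cells (8). On arrays 1 and 2 they were 0.012 and 0.026 for T cells and 0.008 and 0.031 for macrophages and monocytes. For dendritic cells they were -0.008 and 0.048. The median of granulocyte and mast cell genes (5 measured) was -0.10 at percentile 4.17, or 2.12 after scaling between the arrays, but below 0.01 in size on array 1 and -0.08 on array 2, both inside the random range. For erythroid and megakaryocyte cells (3 measured) it was 0.03, with 0.14 on array 1 and -0.08 on array 2. For stromal cells (10 measured) the median was below 0.01 in size. Natural killer cell genes (5 measured) had a median of 0.12 at percentile 97.49, with 0.15 on array 1 and 0.09 on array 2, at the edge of the random range (inside it under 4 of 12 alternatives and above it under the others), with Il2rb at 0.45 ± 0.10 and Prf1 at 0.34 ± 0.13. Responses to the stimuli were mixed. The interleukin-4 list lay at percentile 44.3, but at 0.69 on array 1 (median -0.135) and at 90.5 on array 2 (median 0.11), with Cish at -0.48 ± 0.01 and Socs3 at -0.45 ± 0.04, and the Toll-like receptor and NF-kappaB list at percentile 66.7 (2.75 on array 1 and 89.8 on array 2), with Il10 at -0.25 ± 0.01 and Cd40 at 0.25 ± 0.04. Apoptosis regulators had a median of 0.04 on the mean, -0.035 on array 1, 0.08 on array 2 and -0.065 with the mean of all probes. The microRNA machinery had a median of -0.07, with Ago2 at -0.28 ± 0.02, although another of its 4 probes gave 0.12. Heat shock genes lay at -0.04 (0.03 on array 1, -0.105 on array 2 and 0.02 with the mean of all probes), respiratory chain genes at percentile 33.3 and housekeeping genes at 0.07 (-0.125 on array 1 and 0.36 on array 2). Without the 4 saturated housekeeping genes that median was 0.23, at percentile 99.6.

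Across all measured genes the log2 ratios of the arrays were hardly related, with Pearson's r = 0.029 and Spearman's rho = 0.088, over genes that are not independent replicates. Without the 437 saturated genes, r was 0.223 and rho 0.14. By intensity, r was between 0.19 and 0.28 in deciles 3 to 9 and -0.384 in decile 10, the brightest. All 22 ribosomal protein genes were saturated, with a median log2 ratio of -0.95 on array 1 and 0.99 on array 2, and 375 genes were saturated in Cy5 on both arrays. In 28 genes both RNAs were saturated on both arrays and no fold is given. The median SD between arrays over all genes was 0.13.

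**Figure D3:**
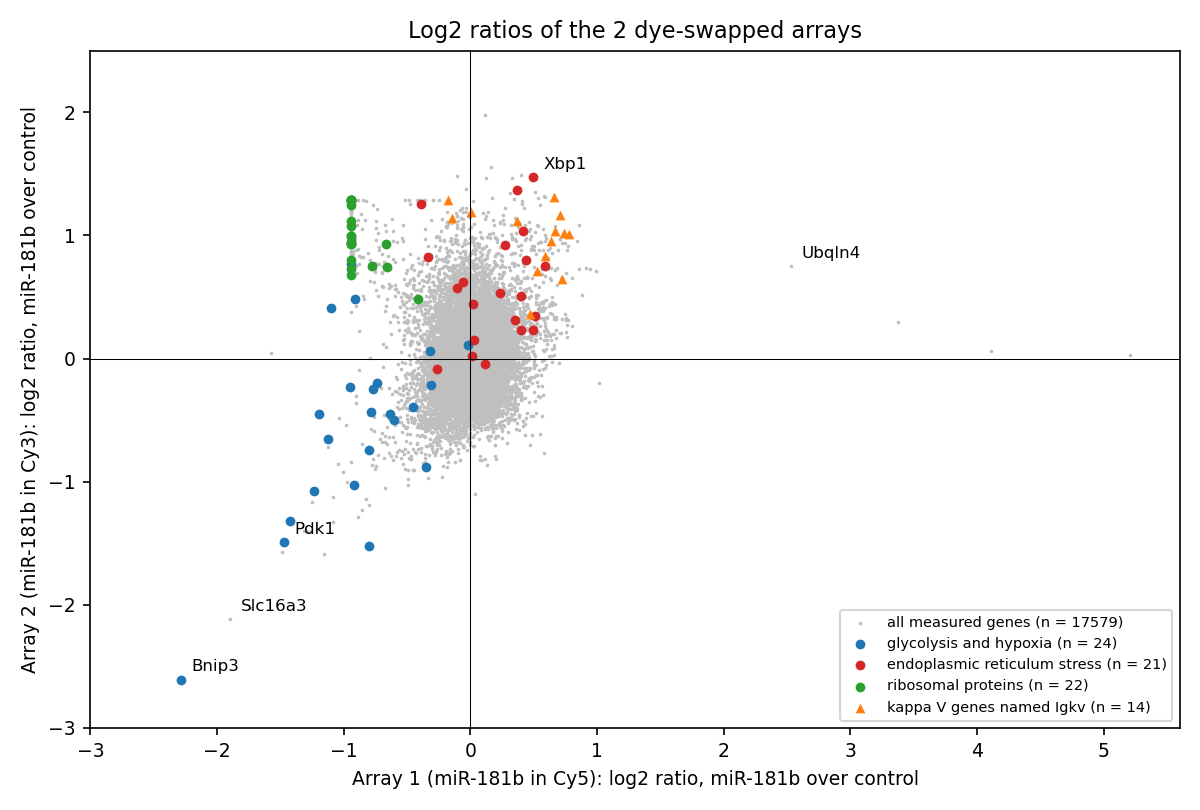
Log2 ratio of each measured gene on array 1 (x axis) and array 2 (y axis), both miR-181b over control, with all 17579 genes in grey. Members of the glycolysis, endoplasmic reticulum stress and ribosomal protein lists and the 14 kappa V genes named Igkv are in colour. Bnip3, Slc16a3 and Pdk1 lie low on both arrays, the Igkv genes mostly high on both, and saturated ribosomal protein genes negative on array 1 and positive on array 2.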

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

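Leaving saturated genes out and scaling between the arrays were tests chosen after the results were seen. The planned comparison of genes by 3' untranslated region site was not run. With 1 RNA pair, the arrays alone show technical spread only, and signal over background limits dim genes to bounds.

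The count of genes at least 2-fold lower in miR-181b cells was 17 and became 33 with the scanner's log ratio, 31 with the deposited table, 56 with median centring, 90 at 1.5-fold and 94 by the scanner p-value, and all 17 genes were kept in each of these. The count of genes at least 2-fold higher in miR-181b cells was 1 and became 3, 5, 0, 144 and 83 under the same settings, and 0 among genes above the median intensity. Each array alone gave between 5 and 210 higher genes. By construction a lower threshold, here also without a minimum for each array alone, admits more genes. For the other settings the cause was not tested. With median centring the median of all genes was -0.20, and the 1.5-fold split was 6 higher to 908 lower against 144 to 90.

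With median centring the lists of mitotic genes were at -0.55, glycolysis and hypoxia at -0.98, cholesterol synthesis at -0.69, MAP kinase feedback at -0.40 and histones at -0.56. Endoplasmic reticulum stress genes turned to -0.016, which is 0.19 above all genes and still above random lists. Histones were at -0.135 with the mean of all probes, for which the cause was not tested. Scaling between the arrays ended the call of the B cell identity list (0.04, percentile 85.1) and put ribosomal proteins (-0.12, percentile 0.38) and granulocyte and mast cell genes (-0.12, percentile 2.12) below random lists. The number of low lists was between 6 and 8 on each array alone. Pearson's r between arrays was 0.233 and Spearman's rho 0.283 with median centring, and r was 0.223 without saturated genes, where fewer genes entered. Without loess 23 of 29 list medians and 100 of 134 named genes' values moved by more than the spread between arrays, and 16 and 28 changed sign. Under the other alternatives that used both arrays, 8 of 284 list medians and 41 of 1302 gene values moved by more, and 20 and 9 changed sign. On each array alone 16 of 58 list medians and 10 of 268 gene values changed sign, and the spread is no yardstick there, being made of the same difference.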

Other observations

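The variable-segment groups, the gene families and, except for the test without loess, the tests of explanations below were chosen after the results were seen. The comparison of genes by miR-181 site used probe sequences. It was not the planned comparison of 3' untranslated regions, which was not run.

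Heavy-chain and kappa immunoglobulin variable genes were mostly higher in the miR-181b cells. Of 79 measured, 71 were higher on both arrays, and they made up 57 of the 144 genes at least 1.5-fold higher on the mean. Heavy-chain V genes (38 measured) had a median of 0.66, with 0.42 on array 1 and 0.96 on array 2. Kappa V genes (41 measured) had a median of 0.69, with 0.57 on array 1 and 0.96 on array 2. Members were saturated in 8 and 10 cases, and without them the medians were 0.68 and 0.73. V genes are similar in sequence, so their probes can share transcripts and are not independent.

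Among 222 gene families of at least 8 members, 3 were above random lists on both arrays and 0 below. These were the Igkv genes (median 0.73), the genes whose name begins with Sec (0.13) and the Speer genes, a mouse-specific family (0.12). Apart from Speer6-ps1 the Speer genes were dim, with mean log2 intensities between 6.71 and 7.43. Their median was between 0.084 and 0.248 under the alternatives. Families were formed by name, so beside coat and translocation genes the Sec group holds the fucosyltransferase gene Sec1 and lipid-binding Sec14l genes. Of 27 Sec genes, 11 were higher and 4 lower on both arrays, and the coat components Sec31a (0.30 ± 0.16) and Sec24c (0.27 ± 0.04) were among the higher, while the coat component Sec24b (-0.14 ± 0.08) and the translocation gene Sec61a2 (-0.15 ± 0.06) were lower. Without loess the Sec median was -0.128, against -0.20 for all genes. Sec16a, which marks export sites of the endoplasmic reticulum, was at 0.38 ± 0.36, with another probe at 0.11.

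The lower glycolysis and hypoxia genes were weighed first. Dye bias alone would put the list on opposite sides of 0. The array nearer to 0 gave -0.44, but this value had been seen beforehand. It describes the list and is no separate test. With median centring in place of loess, the list also lay at percentile 0. The random lists matched its intensity, so a trend with intensity moves both alike. That percentile could hardly have differed and does not decide on loess. A difference between the cultures other than the vector, such as cell density or oxygen, cannot be told apart from the vector, since there was 1 culture per vector. An effect of the microRNA stays open as untested.

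The higher secretory and V genes were weighed next. For the endoplasmic reticulum stress list, dye bias alone would also put the arrays on opposite sides of 0. Its median was 0.27 on the array nearer to 0, but the list was picked as high on both arrays. That value is therefore no separate test. A dye share in its size stays open, since the list also stood apart in the dye contrast (-0.15). The V genes are not part of this list, and dye bias was not tested for them. A larger share of antibody-secreting cells in the miR-181b culture may contribute: heavy-chain V genes, a group apart from the kappa genes first noticed, lay at percentile 100. That value cannot decide the question, since the same cells make both chains and both could rise without a change in that share. The plasma cell list had a median of 0.10 on array 1, at percentile 97.3 and inside the random range, and 0.37 on array 2. Whether such a share differed, and whether the vector or the culture set it, was not tested.

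Genes whose probe holds a miR-181 site (189 measured) had a median log2 ratio of -0.006, with 0.01 on array 1 and -0.05 on array 2. It lay at percentile 82.3 of random lists matched on intensity and probe GC content, inside their range of -0.041 to 0.008. A probe covers only part of a transcript.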
